A study of Danio rerio with 3 samples.

How the data were processed

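Small RNA was sequenced from retinas of adult albino zebrafish at 3 time points. The labels name the libraries 0h, 72h and 28d, and they describe the later 2 as light-damaged. Each time point has 1 library. Per the labels' protocols, total RNA was separated on a gel, RNA of 15 to 30 nt was selected, and adapters were ligated to both ends before RT-PCR. Bowtie and the genome build Zv9 are named in the submitters' processing notes, without a version or role. The trimming, the mismatches allowed and the miRNA release are not given in the sources used here.

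The files deposited by the authors list read counts, as whole numbers, for each distinct sequence under each miRNA precursor, with the start position in the precursor. They are not normalized. They give precursor names and sequences rather than mature miRNA names, so each row is a sequence variant and not a miRNA. The record of files ties none of them to a sample. Each was assigned to a time point because its deposited name carries the title of 1 sample and of no other. The 0h file has another layout from the other 2, including 215 subtotal lines, which were left out of the counts. It also lists no sequence with 1 read, while the 72h and 28d files do.

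A sequence that occurs in several precursors is listed under each of them with its full count. Summing the lines as deposited would therefore give 3.73, 2.77 and 3.01 times the reads at 0h, 72h and 28d. Here each sequence was counted once. Within a precursor, the most abundant sequence set the first arm, and the most abundant sequence starting at least 25 nt away set the opposite arm. Reads starting within 6 nt of an arm's main sequence were assigned to that arm. Arms with the same main sequence were merged into 1 mature product, so copies such as the 6 miR-124 precursors form a single miR-124-3p. The mature names, including 5p and 3p, were given here from these arms. Sequences that fit more than 1 product went to the product with more reads of its own. They made up 0.409%, 0.312% and 0.422% of the reads, and close paralogs remain uncertain to that extent. Reads outside both arms made up 0.00504%, 0.0148% and 0.00749%. No genome was used here, so positions refer to precursors and no chromosome coordinates are given.

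The depth was 15390378 reads in 3356 sequences at 0h, 27119602 reads in 5328 sequences at 72h and 27385758 reads in 4915 sequences at 28d. Levels are counts per 1000000 miRNA reads (CPM). Of 413 products, 228 had a mean CPM of at least 10 over the 3 libraries and were compared. A miRNA was listed as higher or lower when its CPM ratio was at least 2-fold and the 95% interval of the ratio excluded 1. The interval is the exact conditional (Clopper-Pearson) interval for 2 Poisson counts. Reads were amplified without molecular identifiers, so intervals cover counting error only. A count of 0 entered ratios at a floor of 3 counts. With 1 library per time point no significance test was possible, and none was made.

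The 18 miRNA lists hold all variants of the named families. They are let-7, the miR-183 cluster, neuronal, miR-181, miR-29, miR-17-92 and paralogs, miR-130-301, miR-430, leukocyte, erythroid, vascular, muscle, pigment epithelium and lens, surface epithelium, liver and gut, the miR-23-24-27 cluster, stress and hypoxia, and a follow-up list. The follow-up list holds miRNAs remembered as studied further by the group that made these data. They were chosen on these or related samples and are not independent evidence. For lists of at least 3 measured members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean expression. A list was said to stand apart at or below the 2.5 percentile or at or above the 97.5 percentile, as a description of these libraries.

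The lists, thresholds, comparisons, alternatives named first below and the rule for naming miRNAs were fixed before the data were examined. The rule names, per comparison, the 10 miRNAs with the largest ratio in each direction among listed miRNAs with a mean CPM of at least 100, the members of the lists at that level, and the 10 most abundant miRNAs. Other miRNAs are said in the text to have been named after their values were seen.

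The time course counted how many miRNAs listed at 72h lay within 2-fold of 0h at 28d. It was set beside 100 draws of a 28d library from the 0h profile and 100 from the 72h profile, with Poisson noise only. The alternatives were TMM factors from edgeR 4.0.16, size factors from DESeq2 1.42.0, library sizes without the 10 most abundant miRNAs, no filter on level, a mean CPM of at least 100, thresholds of 1.5-fold and 4-fold, a pseudocount of 5 CPM, family and arm summed, and the most abundant sequence only. Both packages were used for scaling factors alone, under R 4.3.3. Further alternatives chosen after seeing the data were reads of up to 22 nt only, sequences with at least 2 reads only, precursor lines summed as deposited, shared sequences left out, and miR-21-1-3p left out. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

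The calculation was tested on simulated counts drawn from the 0h profile at the real depths, with Poisson noise only. The interval assumes the same noise, so the test checks the calculation. It gives no error rate for real libraries, whose spread is not known. For 72h over 0h, the intervals covered the true ratio for 96.0% of 224 products. All of the 44 products altered 3-fold and all of the 35 altered 6-fold were listed in the right direction (100%), and 0% of the 29 altered 1.5-fold and 0% of the 116 unaltered products were listed.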

Results

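The series profiled miRNAs in the zebrafish retina before, during and after regeneration from light damage. Intense light kills photoreceptors in albino fish, and Müller glia, the support cells that span the retina, then divide and replace them. The data are 3 small RNA libraries, 1 each at 0h, 72h and 28d, with 15390378, 27119602 and 27385758 miRNA reads. There are no replicates, so no difference below has a replicate check, and each ratio compares 2 libraries rather than 2 conditions. Levels are reads per 1000000 miRNA reads (CPM), and the 95% intervals cover counting error only.

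The most abundant miRNA was miR-124-3p, a neuronal miRNA with the main sequence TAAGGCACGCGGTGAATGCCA, at a mean of 272050 CPM over the 3 libraries. It was followed by miR-181a-5p, found in inner retinal neurons, and by miR-21-5p, a miRNA of injury and proliferation. The other members of the 10 most abundant were miR-181b-5p, let-7a-5p, miR-22a-3p, miR-9-5p and the miR-183 cluster products miR-183-5p, miR-96-5p and miR-182-5p, which mark photoreceptors and other sensory cells. The 10 most abundant miRNAs of each single library, not always the same ones, took 74.5% of reads at 0h, 74.3% at 72h and 70.3% at 28d. Levels of the 228 compared miRNAs were correlated across miRNAs between libraries, which are not independent replicates, with a Spearman's rho of 0.907 for 72h and 0h, 0.954 for 28d and 72h, and 0.963 for 28d and 0h.

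The 0h library held few long reads. Reads of 23 nt or more made up 7.73% of reads at 0h, 29.7% at 72h and 17.9% at 28d. Part of the 72h share came from the most abundant miRNA of that library. That miRNA took 21.4% of all reads at 72h and 3.50% at 28d. Of its own reads, 68.4% at 72h and 17.7% at 28d had 23 nt or more. Shares without it were not computed, so the higher share at 72h than at 28d may reflect its level rather than the library. For the 30 compared miRNAs whose main sequence has 23 nt, the median log2 ratio of 72h over 0h was 1.09, against -0.04 for the 144 with 22 nt. Values from reads of up to 22 nt are therefore given beside 23-nt miRNAs in comparisons with 0h.

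**Figure D1:**
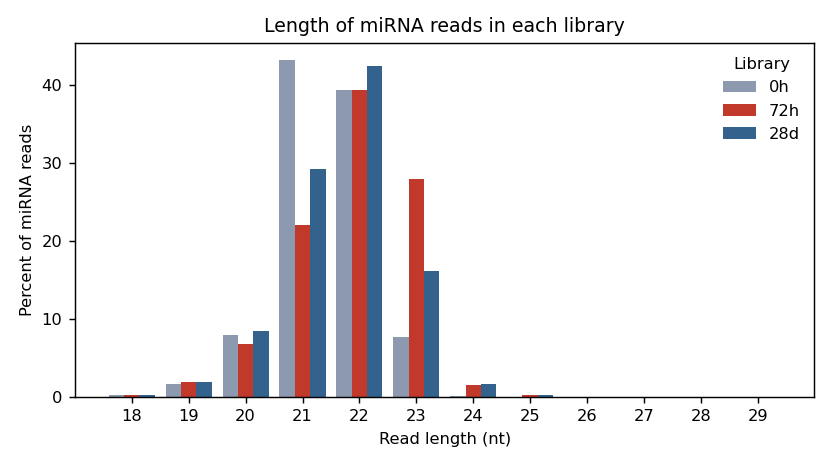
Percent of miRNA reads (vertical axis) at each read length in nt (horizontal axis) in the 0h, 72h and 28d libraries, 1 bar per library. Reads of 23 nt made up 7.68% at 0h, 27.9% at 72h and 16.1% at 28d, and reads of 21 nt 43.2%, 22.1% and 29.2%. The bars sum all miRNAs, so they also reflect which miRNAs were abundant in each library.

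The first comparison asked which miRNAs differed during regeneration, at 72h, from the undamaged retina. Among miRNAs with a mean CPM of at least 100, injury and immune miRNAs stood highest. miR-21-5p was 19.6-fold higher at 72h (interval 19.5 to 19.7), at 10930 CPM at 0h and 213959 CPM at 72h, which made it the most abundant miRNA of that library. miR-146a-5p, which NF-κB induces and which dampens that pathway, was 40.5-fold higher (37.0 to 44.5), and miR-223-3p, a miRNA of myeloid cells, 8.99-fold higher (8.18 to 9.90). At the other end, miR-184-3p, known from cornea, lens and pigment epithelium, was 25.2-fold lower (23 to 27.7), and neuronal miR-124-3p was 2.25-fold lower, at 40.2% of reads at 0h and 17.9% at 72h.

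In all, 40 of the 228 miRNAs were at least 2-fold higher at 72h, 42 were at least 2-fold lower and 146 were neither. The median log2 ratio of all 228 was 0.06. With reads of up to 22 nt the counts were 47 and 29, which kept 30 of the 40 and 26 of the 42, so the higher made up 61.8% rather than 48.8% of the listed. Among those with a mean CPM of at least 100, the next largest ratios on the higher side were those of miR-27c-3p, 7.47-fold (7.14 to 7.83), miR-216b-5p, 4.19-fold (3.93 to 4.48), miR-135c, 3.77-fold (3.62 to 3.93), and the shared product of miR-142a and miR-142b, a miRNA of blood cells, 3.22-fold (3.0 to 3.46). miR-217-5p, miR-16b-5p and miR-15b-5p completed the 10, at log2 ratios of 1.42, 1.39 and 1.36. With only the most abundant sequence of each miRNA, miR-15b-5p had 0.18, short of 2-fold. miR-16 and miR-15 are related miRNAs that restrain the cell cycle. With reads of up to 22 nt alone, the log2 ratio was 3.21 rather than 4.29 for miR-21-5p, 4.20 rather than 5.34 for miR-146a-5p and 1.57 rather than 1.92 for miR-135c, all of which have a 23-nt main sequence. With only that most abundant sequence, it was higher instead, at 6.86 for miR-21-5p, 6.68 for miR-146a-5p and 2.67 for miR-135c. In that setting miR-27c-3p had 3.49 rather than 2.90 and miR-142a/miR-142b-3p 2.54 rather than 1.69.

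On the lower side, miR-729-3p was 6.50-fold lower (6.38 to 6.63), miR-182-3p 5.90-fold lower (5.55 to 6.29), and miR-129-2-3p, a 3p product of a neuronal miRNA, 5.67-fold lower (5.53 to 5.81). miR-19b-3p was 4.07-fold lower (3.99 to 4.15) and miR-101a-3p 3.62-fold lower (3.55 to 3.68). The log2 ratios of miR-124-4-5p, miR-19a-3p, miR-129-1-3p and miR-125c-5p were -1.78, -1.76, -1.74 and -1.65. With only the most abundant sequence, miR-129-1-3p had -3.21, miR-184-3p -5.61 rather than -4.66, and miR-729-3p -3.42 rather than -2.70. For miR-124-3p the log2 ratio was -1.17, and -0.78 with reads of up to 22 nt, short of 2-fold. Without miR-21-5p in the total, miR-124-3p made up 40.6% at 0h and 22.8% at 72h, a log2 ratio of -0.84, or -0.65 with reads of up to 22 nt. Part of its lower share thus reflects the reads taken by miR-21-5p.

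**Figure D2:**
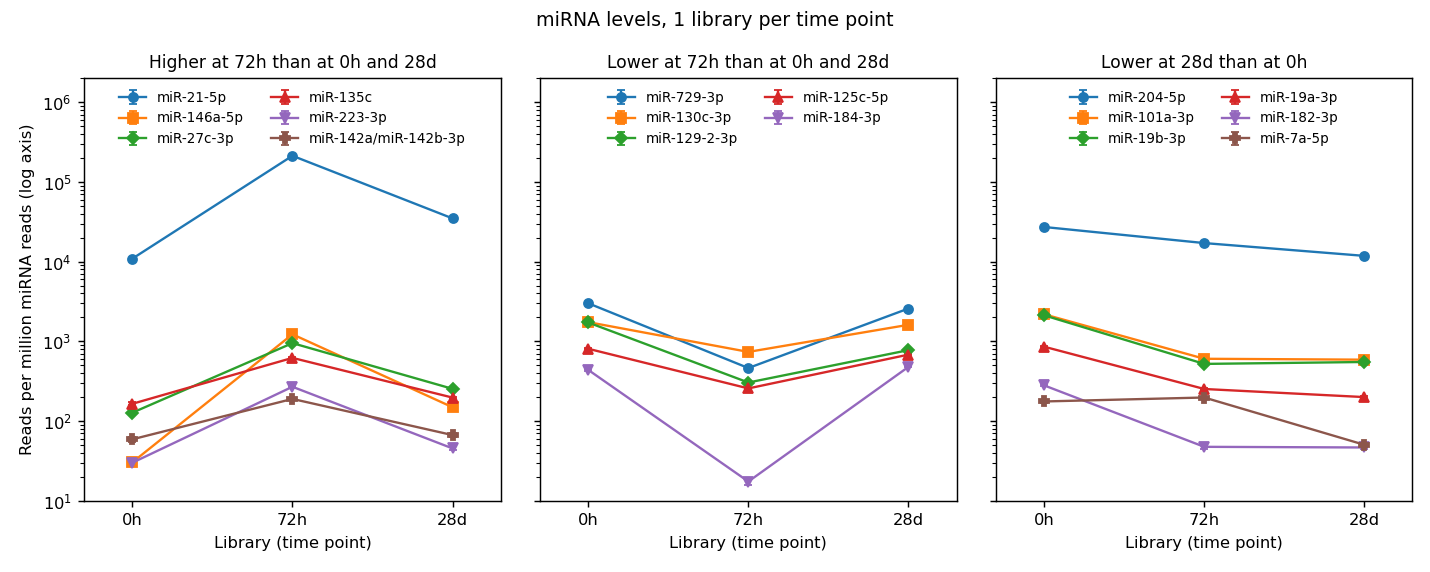
Level of selected miRNAs in reads per 1000000 miRNA reads on a log axis (vertical) in the 0h, 72h and 28d libraries (horizontal), with bars for the 95% Poisson interval of the count, mostly smaller than the symbols. miR-21-5p stood at 10930, 213959 and 35012 CPM and miR-184-3p at 440, 17.4 and 480 CPM, while miR-7a-5p was lower at 28d than in both other libraries.

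Among the fixed lists, 5 stood apart at 72h over 0h. Alternatives in which the miR-17-92 list or the miR-23-24-27 cluster lay inside the bound are given in the next paragraph. Of 10 measured leukocyte and inflammation products, 7 were higher, 0 lower and 3 neither, with a median log2 ratio of 2.71 (percentile 100), or 1.97 with reads of up to 22 nt. They included miR-21-5p, miR-146a-5p, miR-223-3p and miR-142a/miR-142b-3p, while miR-150-5p, a lymphocyte miRNA, had a ratio of 0.44 on the log2 scale. Every one of these 10 except miR-21-1-3p was also listed at 0h. Whether that sequence was left out of the 0h file is not known, and without it 6 of 9 were higher (median 2.61, percentile 100). Moreover, miR-21-5p and miR-146a-5p are not restricted to leukocytes. Of the 16 products of miR-17-92 and its paralogs, which promote proliferation, 7 were higher, 3 lower and 6 neither (median 0.93, percentile 99.9). The list was divided: miR-20a-5p and miR-18a-5p had log2 ratios of 1.33 and 1.06 and miR-17a-5p 0.95, while miR-19b-3p and miR-19a-3p, of the same family of clusters, had -2.03 and -1.76. Of 9 products of the miR-23-24-27 cluster, tied to vessels and apoptosis, 4 were higher and 0 lower (median 0.89, percentile 98.6), among them miR-27c-3p, miR-23a-3p at 1.15 and miR-24-3p at 1.12. Of 9 surface epithelium products, 5 were lower and 0 higher (median -1.24, percentile 0.665), with miR-200c-3p at -0.58 and miR-141-3p at -0.55 as the only members above 100 CPM. The follow-up list, which is not independent evidence, had 4 of 8 higher and 2 lower (median 1.15, percentile 99.1), with a median of 2.29 for members with a mean CPM of at least 100. Its miR-31-5p, at a mean of 14.6 CPM and named after its values were seen, was 15.7-fold higher (11.3 to 22.5).

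The remaining lists did not stand apart. Of 21 neuronal products, 0 were higher, 6 lower and 15 neither (median -0.15, percentile 20.9), with miR-9-5p at -0.15, miR-128-3p at -0.91 and miR-138-5p at 0.44. The miR-183 cluster had 1 of 6 lower, which was miR-182-3p, and a median of 0.21 (percentile 66.4), with miR-183-5p at 0.21, miR-96-5p at 0.38 and miR-182-5p at 0.23. The let-7 family, which the RNA-binding protein Lin28 restrains, had 1 of 13 higher and 3 lower (median 0.18, percentile 66.2), with let-7a-5p at -0.20 and let-7i-5p at 1.19. The 3 lower were 3p arms at means of 10.6 to 32.5 CPM, and no 5p arm was lower. The miR-181 family had 2 of 7 higher and 2 lower (median -0.64, percentile 10.7), the former being miR-181b-5p at 1.15 and miR-181c-5p at 1.10. The 2 lower were 3p arms at means of 375 and 464 CPM. The 5p arms had means of 2944 to 111828 CPM, and none of them was lower. The miR-130-301 family had 4 of 9 lower (median -0.72, percentile 6.61), with miR-130b-3p at -1.31, miR-130c-3p at -1.24 and miR-130a-3p at -1.03. Vascular products had 3 of 9 higher and 1 lower (median 0.38, percentile 85.3), with miR-222-3p at 1.33, miR-126-3p at 0.31 and miR-145-5p at -1.0. Muscle had 2 of 4 lower (median -0.97, percentile 6.97), miR-29 0 of 4 in either direction (median -0.04, percentile 46.5), and pigment epithelium and lens 1 of 3 lower, which was miR-184-3p (median -0.67, percentile 20.4). Stress and hypoxia had 1 of 11 higher, which was miR-31-5p (median 0.13, percentile 54.3). The erythroid list had 2 members, miR-451 at -0.89 and miR-144-3p at 0.07, and no member of the miR-430 family or of the liver and gut list reached 10 CPM. With reads of up to 22 nt, the median of miR-17-92 and paralogs lay at percentile 97.3, just inside the bound, and that of miR-130-301 at 0.455, outside it. For members with a mean CPM of at least 100, miR-17-92 lay inside as well, at 94.4 with a median of 0.59, and let-7 outside, at 98.3, against 90.1 with reads of up to 22 nt. The miR-23-24-27 cluster lay inside, at 96.0, with family and arm summed. The 23-nt members named above had log2 ratios with those reads of 1.17 for miR-20a-5p, 0.96 for miR-17a-5p, 0.23 for miR-150-5p, 0.84 for miR-138-5p, 0.05 for miR-96-5p, 0.98 for miR-181b-5p, 0.85 for miR-181c-5p, 0.91 for miR-222-3p and -1.03 for miR-145-5p.

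The second comparison set 28d, after regeneration, against 72h. The injury and immune miRNAs were lower at 28d and miR-184-3p was higher. The median log2 ratio of all 228 miRNAs was 0.20 with CPM and 0.01 with TMM factors, so the folds here are relative to the median, while the counts of miRNAs use CPM as planned. Relative to the median, miR-146a-5p was 9.48-fold lower at 28d (9.18 to 9.80), miR-21-5p 7.03-fold lower (7.02 to 7.05), miR-223-3p 6.84-fold lower (6.44 to 7.27) and miR-27c-3p 4.31-fold lower (4.20 to 4.43). miR-184-3p was 23.9-fold higher (21.8 to 26.3) and miR-729-3p 4.86-fold higher (4.76 to 4.95).

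At 28d, 19 miRNAs were at least 2-fold higher than at 72h, 17 lower and 192 neither. With TMM factors, 11 were higher and 22 lower, so the share of the higher among the listed was 33.3% rather than 52.8%. miR-7a-5p, a miRNA of neurons and endocrine cells, was 4.52-fold lower at 28d relative to the median (4.26 to 4.79), although it had differed little between 0h and 72h, at 176 and 198 CPM. Its level at 28d was 50.4 CPM. miR-135c was 3.63-fold lower, the shared miR-142a and miR-142b product 3.27-fold lower and miR-23a-3p 2.42-fold lower, the last with a CPM log2 ratio of -0.95, short of 2-fold, when only its most abundant sequence was counted. On the higher side came miR-210-3p, a miRNA induced by hypoxia, at 2.74-fold (2.70 to 2.79), then miR-125c-5p at 2.31-fold, miR-129-2-3p at 2.22-fold, miR-181a-1-3p at 2.10-fold and miR-130b-3p at 2.09-fold. miR-130a-3p, miR-130c-3p and the shared miR-124-2/3/5-5p were at least 2-fold higher in CPM, at log2 ratios of 1.14, 1.13 and 1.03, and at 0.95, 0.94 and 0.84 with TMM factors.

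In this comparison 4 lists stood apart. Leukocyte products were lower in 7 of 10 and higher in 0 (median log2 relative to all miRNAs -1.87, percentile 0), and in 6 of 9 without miR-21-1-3p (median -1.71, percentile 0.005). In CPM the list median was -1.67, and -2.57 for members with a mean CPM of at least 100. The miR-17-92 list had a median of -0.63 (percentile 0.12) with 1 of 16 lower and 15 neither. The miR-181 family had 2 of 7 higher (median 0.48, percentile 98.1), both of them passenger arms, miR-181a-1-3p among them. This call was lost with reads of up to 22 nt, at percentile 96.4, with a pseudocount of 5 CPM, at 94.6, and at a mean CPM of at least 100, at 75.2. The follow-up list had 5 of 8 lower (median -1.91, percentile 0), namely miR-146a-5p, miR-31-5p, miR-7a-5p, miR-27c-3p and miR-142a/miR-142b-3p. Of neuronal products 3 of 21 were higher and 0 lower (median 0.17), with miR-124-3p at 0.19 relative to all miRNAs. Of miR-130-301 products 3 of 9 were higher and 0 lower (median 0.15). The miR-183 cluster had 0 of 6 and let-7 had 1 of 13 higher, and surface epithelium had 2 of 9 higher (median 0.31, percentile 95.5, or 98.4, outside the bound, with family and arm summed). With TMM factors the counts higher were 1 of 7 for miR-181, 2 of 21 for neuronal, 1 of 9 for miR-130-301 and 0 of 13 for let-7, and miR-17-92 had 2 of 16 lower. The 23-nt miRNAs miR-21-5p and miR-146a-5p differed less with reads of up to 22 nt, at log2 ratios of -1.45 and -1.57 against -2.61 and -3.04 with reads of all lengths. They differed more with only the most abundant sequence, at -4.45 and -4.62, as did miR-184-3p, at 6.11 rather than 4.78, and miR-27c-3p, at -2.52 rather than -1.91.

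**Figure D3:**
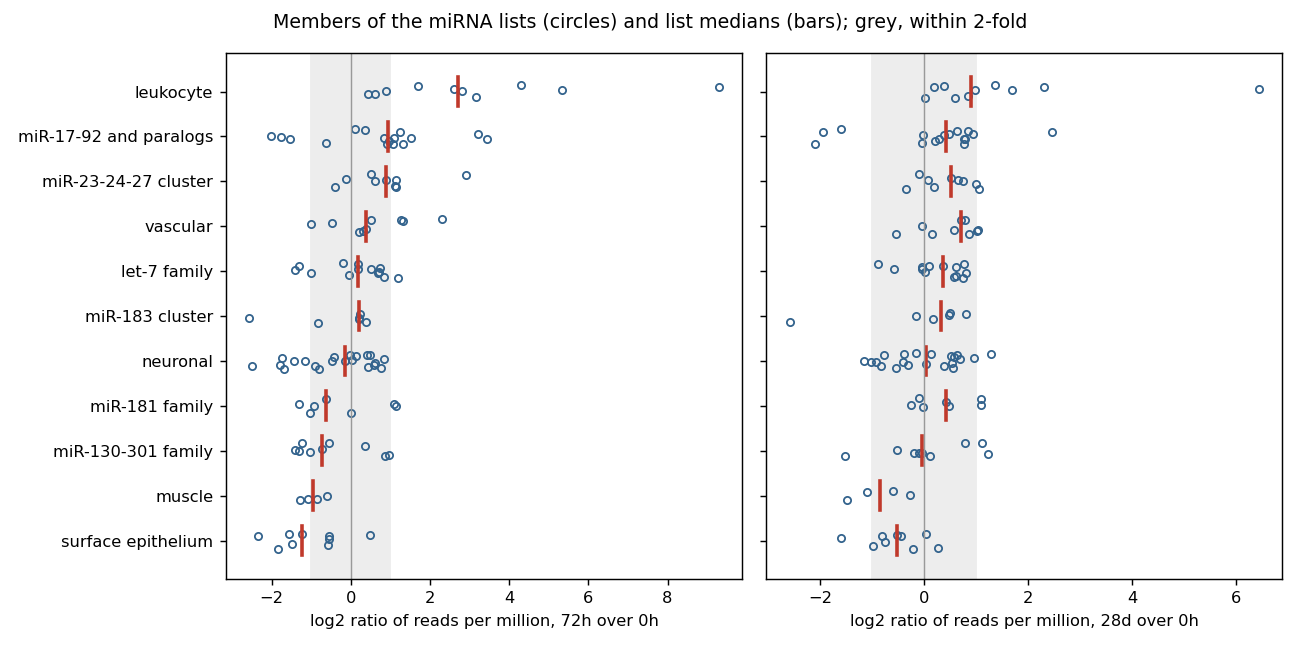
log2 ratio of reads per 1000000 miRNA reads (horizontal axis) of each member of 11 lists (circles) with the list median (bar), for 72h over 0h (left) and 28d over 0h (right), in a grey band where within 2-fold. The rightmost leukocyte circle is miR-21-1-3p, listed with 0 reads at 0h and placed with a floor of 3 counts. Leukocyte medians were 2.71 at 72h and 0.91 at 28d, and surface epithelium medians -1.24 and -0.53.

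The third comparison asked how far the retina at 28d differed from the undamaged one. miR-21-5p and miR-146a-5p remained above their 0h levels, while miR-184-3p stood at 480 CPM against 440 at 0h. The median log2 ratio of all 228 miRNAs was 0.26 with CPM and 0.09 with TMM factors, and folds are again relative to the median. miR-146a-5p was 4.10-fold higher at 28d (3.73 to 4.52), miR-216b-5p 3.09-fold higher (2.89 to 3.30) and miR-21-5p 2.67-fold higher (2.66 to 2.68). miR-182-3p was 7.22-fold lower (6.78 to 7.69), miR-19a-3p 5.15-fold lower (4.99 to 5.31), miR-19b-3p 4.62-fold lower (4.53 to 4.71) and miR-101b-3p 4.55-fold lower (4.30 to 4.81).

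In CPM, 22 miRNAs were at least 2-fold higher at 28d than at 0h, 23 lower and 183 neither. With TMM factors the counts were 11 and 28, so the higher made up 28.2% rather than 48.9% of the listed. Lower miRNAs also included miR-101a-3p, 4.45-fold, miR-7a-5p, 4.20-fold, miR-190b-3p, 2.87-fold, miR-204-5p, a miRNA of pigment epithelium, lens and Müller glia, 2.76-fold (2.75 to 2.78), miR-129-2-3p, 2.67-fold, and miR-737-5p, 2.58-fold. The CPM log2 ratio of miR-129-2-3p was -0.82 with only its most abundant sequence and -0.99 with reads of up to 22 nt, where miR-737-5p had -0.94, all short of 2-fold. miR-204-5p stood at 27321 CPM at 0h, 17164 at 72h and 11857 at 28d. Among the higher, miR-129-5p was 2.03-fold higher (2.0 to 2.07), opposite in direction to miR-129-2-3p from the other arm. The remaining 6 of the 10, miR-454a-3p, miR-454b-3p, miR-730-3p, miR-181b-5p, miR-181c-5p and miR-456-3p, had CPM log2 ratios of 1.23, 1.11, 1.10, 1.09, 1.09 and 1.01. With TMM factors they had 1.06, 0.94, 0.93, 0.92, 0.92 and 0.84. Those with a 23-nt main sequence had log2 ratios of 0.60 for miR-454a-3p, 0.31 for miR-454b-3p, 0.63 for miR-181b-5p and 0.65 for miR-181c-5p with reads of up to 22 nt, and miR-21-5p and miR-146a-5p had 1.76 and 2.62. With only the most abundant sequence, the first 4 had larger ratios instead, 1.92, 1.74, 1.54 and 1.55, and miR-21-5p and miR-146a-5p had 2.41 and 2.06.

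At 28d over 0h, 3 lists stood apart. Leukocyte products were higher in 4 of 10 and lower in 0 (median relative to all miRNAs 0.64, percentile 99.9), and higher in 3 of 9 without miR-21-1-3p (median 0.58, percentile 99.5). The 4 were all products of miR-21 and miR-146, which are not restricted to leukocytes, while miR-142a/miR-142b-3p, miR-223-3p and miR-150-5p were neither, at CPM log2 ratios of 0.18, 0.60 and 0.84. Vascular products were higher in 2 of 9 in CPM and in 0 with TMM factors (relative median 0.44, percentile 98.6), with miR-126-3p at 1478 CPM against 910 CPM at 0h. Surface epithelium products were lower in 1 of 9, or 2 with TMM factors (median -0.79, percentile 2.01). With reads of up to 22 nt the vascular list lay at percentile 80.0 and surface epithelium at 3.47, both inside the bounds, and the leukocyte list at 99.1. They were likewise inside with family and arm summed, at 93.2 and 4.87, and the vascular list lay at 92.6 at a mean CPM of at least 100. The miR-17-92 list had 1 of 16 higher and 3 lower, neuronal products 1 of 21 higher and 2 lower, the miR-183 cluster 1 of 6 lower and let-7 0 of 13 in either direction. With TMM factors neuronal products had 3 lower and let-7 had 1.

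The time course asked whether miRNAs that differed at 72h were back near their 0h level at 28d. Of the 40 higher at 72h, 23 were within 2-fold of 0h at 28d, including miR-223-3p, miR-135c and miR-142a/miR-142b-3p. The other 17 were still at least 2-fold higher, including miR-21-5p, miR-146a-5p and miR-216b-5p. Among the 23, miR-27c-3p lay at the edge, with a log2 ratio of 0.995 at 28d over 0h. With reads of up to 22 nt it had 3.29 at 72h over 0h and -2.13 at 28d over 72h, so it stayed over 2-fold above 0h. Of the 42 lower at 72h, 25 were within 2-fold of 0h, including miR-184-3p, miR-729-3p, miR-125c-5p, miR-130a-3p, miR-130b-3p and miR-130c-3p, and 17 were still lower, including miR-182-3p, miR-19a-3p, miR-19b-3p, miR-101a-3p and miR-129-2-3p. This even split depended on the setting: with TMM factors 9 of 40 were still higher, and 20 of 40 still lower, and 9 of the 17 and 17 of the 17 were kept. With CPM and reads of up to 22 nt, 17 of 47 were still higher and 16 of 29 still lower. At 1.5-fold, 43 of 63 were still higher and 32 of 70 still lower. None of the 82 had crossed to the opposite side by 2-fold (0). In total 48 of 82 were within 2-fold of 0h, against 80 to 81 in 100 draws of a 28d library from the 0h profile and 0 to 6 in 100 draws from the 72h profile. The draws hold counting noise only, without the spread between libraries, which is not known here, so they do not show the count expected from a second undamaged library. Because miRNAs were picked for a difference at 72h, part of any return is built in. The 0h library enters both ratios, so any error in it moves both the same way and builds in persistence.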

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

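The tests in this part were chosen after the files were seen. The reads outside both arms of a precursor belong to no miRNA compared above. A precursor is given where such reads numbered at least 100 and were at least 4 times their share at 0h, with a floor of 3 counts.

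For mir-21-2, 623 reads lay outside the arms at 72h, against 4 at 0h and 7 at 28d. For mir-21-1 there were 177 at 72h, 4 at 0h and 36 at 28d. miR-21-5p itself had a log2 ratio of 4.29 at 72h over 0h, and these reads outside the arms were not set against its level. mir-2190 had 1270 at 72h, 73 at 0h and 253 at 28d, and its reads began at 59 positions, with 23.5% at the most frequent start. mir-125b-2 had 123 at 72h, 12 at 0h and 22 at 28d. let-7a-6 had 103 at 72h, 14 at 0h and 96 at 28d. The 0h file lists no sequence with 1 read, so its counts of such rare reads are low by an amount that is not known.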

How the results depend on the processing

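The alternatives using reads of up to 22 nt, sequences with at least 2 reads, summed precursor lines, shared sequences left out and miR-21-1-3p left out were chosen after seeing the data, and the others before. With 1 library per time point no library can be left out, and no paired analysis was possible because each group has 1 library. Counts below are of miRNAs higher and lower, in the order 72h over 0h, 28d over 72h and 28d over 0h, where the main counts were 40 and 42, 19 and 17, and 22 and 23. Only counts beyond 1.5 times the main one are given.

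Thresholds and filters moved the counts by construction. They were 63 and 70, 50 and 28, and 69 and 38 at 1.5-fold. At 4-fold they were 15 and 8, 3 and 8, and 4 and 2. Without a filter they were 84 and 77, 34 and 55, and 44 and 49. At a mean CPM of at least 100 they were 19 and 23, 11 and 8, and 10 and 12. Scaling mattered for miRNAs higher at 28d. Of these there were 11 over 72h and 11 over 0h with TMM, 12 and 11 with DESeq2, and 11 and 12 with library sizes without the 10 most abundant miRNAs. With family and arm summed, fewer products were compared, and 27 were lower at 72h and 9 higher at 28d than at 72h. The most abundant sequence alone gave 32 higher at 28d than at 72h and 51 higher than at 0h, and the cause was not tested. Precursor lines summed as deposited, which repeat sequences and merge arms, gave 9 lower at 72h, 10 higher at 28d than at 72h, and 35 higher and 11 lower at 28d than at 0h.

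The number of lists that stood apart was 5, 4 and 3. With family and arm summed it was 3 for 72h over 0h and 1 for 28d over 0h. At 72h the miR-23-24-27 cluster lay inside the bound, at percentile 96.0, and the follow-up list had too few summed members for a value. For 28d over 0h it was also 1 at a mean CPM of at least 100, where the vascular list lay inside the bound and surface epithelium had too few members for a value, and 1 with reads of up to 22 nt. In the time course, 48 of 82 miRNAs were within 2-fold of 0h at 28d, against 29 of 42 at a mean CPM of at least 100, 51 of 80 with TMM and 43 of 76 with reads of up to 22 nt. At 1.5-fold, 57 of 133 were within that threshold.

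Every alternative for single miRNAs was run on the 10 with the largest ratios per comparison and direction, or fewer where fewer qualified. None of these and no list that stood apart changed sign in the alternatives that gave them a value. Other miRNAs named in the text were not run through all of them, and miR-731-5p had 1.48 at 72h over 0h but -0.02 with reads of up to 22 nt. Of the values run, 719 stayed on their side of the threshold or within 0.1 on the log2 scale, 74 ratios came under the threshold used and 40 list medians moved by more. Filters, fold thresholds and leaving out a miRNA outside these sets left each single ratio identical. Except at the 4-fold threshold, such ratios could only stay on their side. They are among the 719, so that count overstates how much was tested. Counting error is small at these depths, and the spread between animals is not known.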

Other observations

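All tests in this part were chosen after the results were seen, except library sizes without the 10 most abundant miRNAs. Several miRNAs in the next paragraphs were likewise named after their values were seen.

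miR-16a-5p and miR-15c-5p, relatives of miR-16b-5p and miR-15b-5p, had log2 ratios of 2.12 and 1.64 at 72h over 0h, against 1.39 and 1.36 for those relatives. miR-462-5p, which belongs to a cluster that interferon induces in fish, had 1.04 at 72h and 1.38 at 28d over 0h. Its cluster partner miR-731-5p had 1.48 at 72h with reads of all lengths and -0.02 with reads of up to 22 nt. miR-125b-5p and miR-99-5p, whose genes neighbour let-7 genes in many animals, had -1.22 and -1.11 at 72h over 0h, or -0.82 and -0.70 with reads of up to 22 nt, while let-7a-5p had -0.20.

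Arms of 1 precursor could differ in direction. miR-182-3p stood at 281, 47.6 and 46.7 CPM at 0h, 72h and 28d, while miR-182-5p stood at 21329, 24932 and 37210 CPM. miR-21-1-3p was listed with 0 reads at 0h, 3322 at 72h and 462 at 28d, and whether its sequence was left out of the 0h file is not known. At the 28d proportion between the arms, the 168211 reads of miR-21-5p at 0h would go with 81.0 reads of miR-21-1-3p. miR-2190-5p, with 11 reads at 0h, 852 at 72h and 16 at 28d, comes from the precursor with scattered read starts named above.

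The first pattern weighed is that miRNAs with a 23-nt main sequence were higher at 72h and 28d than at 0h. The share of reads of 23 nt or more was lowest at 0h in 82.4% of 119 miRNAs, so fewer long reads in the 0h library may account for part of it. With reads of up to 22 nt, the median log2 ratio of the 23-nt miRNAs at 72h over 0h was still 0.70 above that of the 22-nt miRNAs, against 1.13 with all reads, but resampling miRNAs put the difference between 0.23 and 1.10. Whether it is the whole cause therefore cannot be told apart from a difference between time points, since the 0h library is the only one of its group.

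The second pattern is the set of 10 miRNAs with the largest ratios of 72h over 0h among those with a mean CPM of at least 100, led by miR-146a-5p and miR-21-5p. All 10 stayed at least 2-fold higher with reads of up to 22 nt. That setting removes more of the 72h total than of the 0h total, and the median log2 ratio of compared miRNAs was 0.27 rather than 0.06. It could hardly fail for miRNAs with few long reads. For the 23-nt miRNAs miR-21-5p, miR-146a-5p and miR-135c the log2 ratios fell to 3.21, 4.20 and 1.57. Long reads alone therefore do not account for these 3. Library sizes without the 10 most abundant miRNAs shifted every ratio alike by 0.07 on the log2 scale and tested nothing. A few abundant miRNAs with a smaller share of reads at 72h than at 0h would raise the others alike. A larger share at 72h, as for miR-21-5p, would lower them, and such shifts can cancel. The other 218 miRNAs had a median log2 ratio of -0.0003, which argues against a net shared rise as large as the lowest of the 10, 1.36. It does not test either shift by itself. The upper quartile of the 218, 0.54, lay below 1.36 largely because the 10 were picked for the largest ratios, so it decides nothing. Leukocytes in the tissue are a candidate source: their listed miRNAs other than miR-21 and miR-146 had a median log2 ratio of 1.29, below the 1.99 of the 10 and above 0. The sets share miR-223-3p and miR-142a/miR-142b-3p. Because the 10 were picked for the largest ratios, a lower median in the leukocyte set is largely built in and decides nothing. Leukocytes and a response of retinal cells cannot be told apart here, because no library of sorted cells was compared.

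The third pattern is that reads of miRNAs higher at 72h were longer at 72h than at 28d. Of 193 miRNAs used, the 10 higher at 72h than at 28d had a median difference of 0.25 nt, and all 10 were longer at 72h. The median was -0.02 nt for the 16 lower at 72h and 0.01 nt for the 167 within 2-fold. The change was larger for miR-21-5p. The mean length of its reads was 22.65 nt at 72h and 22.01 nt at 28d, with 68.4% and 17.7% of reads at 23 nt or more. let-7a-5p had 21.6 nt in both. Longer reads throughout the 72h library are argued against by a median difference of 0.0167 nt over 193 miRNAs. Across miRNAs, which are not independent replicates, the change in length from 72h to 28d went with the ratio of 28d over 72h. This change is counted opposite to the differences above. Spearman's rho was 0.46, and 0.39 without the 23-nt miRNAs. These correlations describe the pattern and do not show how the longer reads arise.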
